A study of Bos taurus with 9 samples.

How the data were processed

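RNA sequencing was analysed for 9 libraries of Bos taurus embryos made by somatic cell nuclear transfer (SCNT), in 3 groups of 3. The groups were morulae from embryos injected with mRNA coding for KDM6A, morulae from embryos that were not injected, and 8-cell embryos. Per the labels' protocols, the donor cells were fibroblasts of a Holstein fetus, the mRNA was injected 1 h after activation, and morulae were collected on day 5 in pools of 5. The labels place the 8-cell libraries in an earlier series, so developmental stage and source series cannot be told apart in any comparison with them. The labels do not say that the pools of a group came from separate days or batches of oocytes, so p-values measure the spread between these samples, which may be technical in part.

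The deposited files give FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) per gene, per the file headers, rounded to 2 decimals by the authors. Per the submitters' processing notes, bcl2fastq 2.16, HISAT 0.1.6, StringTie 1.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used with the UMD3.1 build. The role and order of each tool, any filter on genes and the handling of reads that map to several places are not given in the sources used here. The files list Ensembl gene identifiers, most of them paired with a symbol. The 6 morula files share 16713 genes, the 3 8-cell files share 16674, and 16129 are in all 9. The file of control morula replicate 1 holds 3038 further rows with no annotated gene identifier, and these entered no comparison. A total of 14527 of the morula genes had a symbol that was usable and belonged to a single row.

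Sequencing depth is not given, and the low values show no steps of whole reads. Ratios of values from 0.15 to below 1 FPKM between library pairs fell in their most common log2 bin of width 0.1 in 3.92% to 8.15% of genes over 36 pairs. No counting intervals are therefore given, and precision is taken from the spread between the 3 libraries of a group. Summed FPKM per library ran from 820300 to 1022000, and the 13 mitochondrial genes held 9.64% to 15.2% of it. No pair of replicates held identical values.

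Fold changes and tests were computed with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean per group and a trended prior variance. A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Folds given as "-fold" are ratios of mean FPKM. Genes with at least 1 FPKM in at least 3 of the 6 libraries compared were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each comparison was fitted on its own 6 libraries. Gene lists, 20 in number, were tested with limma's camera test at a preset correlation of 0.01 between genes, for lists of at least 5 tested members. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. On simulated data with 200 changed genes among the 9777 of the KDM6A comparison, the test recovered 73% of genes changed by 1 log2 unit and 100% of those changed by 2, with 10 false calls. For the control morula and 8-cell comparison the shares were 52% and 99% with 9 false calls, and for KDM6A morulae against 8-cell embryos 50% and 99% with 14. The changed genes were drawn from those with a mean at or above that of 5 FPKM on the log2 scale. The simulated noise was independent between libraries. Recovery of lower genes, or with libraries that deviate together, was therefore not measured.

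The groups, tests, gene lists, naming rule and the alternatives below were fixed before the data were examined. Named in each of the KDM6A and control stage comparisons are the 10 largest rises and 10 largest falls among genes with a usable symbol, no overlap between groups and a mean of at least 5 FPKM in the higher group. Where fewer than 10 passed, the tested genes with the smallest unadjusted p fill the places, as values only. Up to 4 members of each list are named, and a set of chromatin and lineage genes is always given. KDM6B was below the filter in both comparisons, and UTY, KDM4E, MBD3L2, XIST and CDX2 were not analysed here. Genes were assigned to the X chromosome or autosomes by symbol from RefSeq annotation of ARS-UCD2.0, which differs from the authors' build, so no coordinates are given. Of the 9777 genes tested, 9049 (92.6%) had a chromosome.

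The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, rescaling to TPM, quantile normalization, median-of-ratios scaling, all 9 libraries in 1 fit, array weights, a robust prior, an estimated correlation for lists, the replicate number as a block, and each replicate left out in turn. With a replicate left out, a gene still had to reach 1 FPKM in 3 of the remaining libraries. A gene at that level in the reduced group alone was therefore not tested. A threshold of 0.10 on the adjusted p was added after the data were seen. Splits of each 6 libraries into 3 and 3, of which there are 10, were run for each count.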

Results

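Bovine embryos made by somatic cell nuclear transfer, in which the nucleus of a body cell is placed into an egg cleared of its own, were profiled by RNA sequencing. KDM6A is an enzyme that removes methyl groups from lysine in histone H3 (the H3K27 mark, which polycomb complexes lay down on silenced genes). The series asks what supplying KDM6A mRNA does to such embryos. Pools of 5 morulae, the compacting stage before the blastocyst, were compared between KDM6A-injected embryos (3 libraries) and embryos that were not injected (3 control libraries). A further 3 libraries came from 8-cell embryos, the stage around which the bovine embryo begins to use its own genome. The values are FPKM, and the depth of each library is unknown. Between 8923 and 11581 genes or rows per library reached 1 FPKM. Correlations of log2(FPKM + 1) across the 16129 genes in all 9 files were 0.986 to 0.992 within control morulae, 0.983 to 0.993 within KDM6A morulae, 0.973 to 0.979 within 8-cell embryos and 0.822 to 0.893 between control morulae and 8-cell embryos.

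KDM6A transcript was higher in the injected morulae, at 67.6 ± 27.9 FPKM (SD, n = 3) against 11.8 ± 1.81 in controls, a 5.74-fold difference. The 3 injected pools stood at 35.65, 87.58 and 79.44 FPKM, each above the controls at 10.72, 13.86 and 10.74. The log2 fold change was 2.33 (SE 0.304, limma adjusted p = 0.0147), and the exact two-sided permutation test of the gene alone gave p = 0.1, the smallest that 3 against 3 allows. Injected mRNA and the embryo's own transcript cannot be separated in these values. The call was lost without control replicate 3 (adjusted p = 0.115), KDM6A replicate 2 (0.0847) or KDM6A replicate 3 (0.132), with fold changes from 2.10 to 2.73 over the replicates left out. Transcripts of the opposing polycomb enzymes showed no call. EZH2, the H3K27 methyltransferase, was at 25.1 ± 4.16 FPKM in controls and 23.9 ± 3.16 in KDM6A morulae, its partner EED at 63.8 ± 12.4 and 63.35 ± 3.13, and SUZ12 at 28.4 ± 4.66 and 32.3 ± 5.46, with adjusted p of 0.735 to 0.993. KDM6B, a related demethylase, was near the floor at 0.19 ± 0.0557 and 0.19 ± 0.0819 FPKM and was not tested.

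Besides KDM6A, few genes separated injected from control morulae. MBD3L3, a relative of the methyl-CpG-binding protein MBD3, rose 7.62-fold from 3.13 ± 1.99 to 23.8 ± 5.63 FPKM (n = 3 each). Rises were also called for PRSS33, a serine protease, from 1.99 ± 0.509 to 8.80 ± 1.64 FPKM, for CD52, a small surface glycoprotein best known from lymphocytes, from 2.04 ± 0.09 to 8.27 ± 2.26, for TNP2, a chromatin protein of maturing sperm, from 7.06 ± 1.024 to 22.1 ± 3.19, and for TPM2, an actin-binding tropomyosin, from 22.3 ± 6.30 to 61.3 ± 4.90. C3H1orf146 fell from 211 ± 6.79 to 96.3 ± 12.5 FPKM. Log2 fold changes of these 6 genes were between 2.70 and -1.13, with limma adjusted p from 0.0147 to 0.0234. MBD3L3 lost its call without control replicate 2 or KDM6A replicate 2 or 3 (adjusted p up to 0.137). PRSS33, TNP2, TPM2 and C3H1orf146 lost theirs without control replicate 2 or 3 or KDM6A replicate 2 or 3 (up to 0.172), and CD52 lost its call when any library other than KDM6A replicate 1 was left out (up to 0.172). In all, 12 genes rose and 4 fell among 9777 tested, against 1244 at an unadjusted p under 0.05, of which 617 were higher and 627 lower. The 2 groups of 3 did not overlap in 15.7% of genes, where chance gives 10%.

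Further called rows were singled out after their values were seen, since they fall outside the naming rule. ENSBTAG00000023823.1 rose 33.5-fold, from 14.98 ± 5.98 to 503 ± 196 FPKM, with a log2 fold change of 4.99 (SE 0.329, limma adjusted p = 0.000135). The morula files call it CYCS, the electron carrier cytochrome c, and the 8-cell files give it a locus number. A second row named CYCS, ENSBTAG00000022613.3, was at 3849 ± 494 FPKM in controls and 2707 ± 100 in KDM6A morulae (adjusted p = 0.169). How reads were divided between rows sharing a name is not given in the sources used here, so both values are uncertain. The call of ENSBTAG00000023823.1 was kept under each of the 10 alternatives run gene by gene. These were a pseudocount of 0.1, quantile normalization, median-of-ratios scaling, the replicate block and each replicate left out. It was lost with no filter, where 0 genes were called. ZNF41, a zinc finger gene, rose from 0.167 ± 0.215 to 4.48 ± 0.801 FPKM. ENSBTAG00000009849.3, which only the 8-cell files name, as PLAC8 and together with another row, fell from 290 ± 65.5 to 65.7 ± 31.5 FPKM, a call lost without control replicate 2 or 3 or KDM6A replicate 3 (adjusted p up to 0.140). Of the 12 rises, 5 were in rows at 104 to 526 FPKM in 8-cell embryos and at 0 to 3.13 in control morulae. They included MBD3L3 (526 ± 113 in 8-cell embryos) and ZNF41 (123 ± 7.09).

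**Figure D1:**
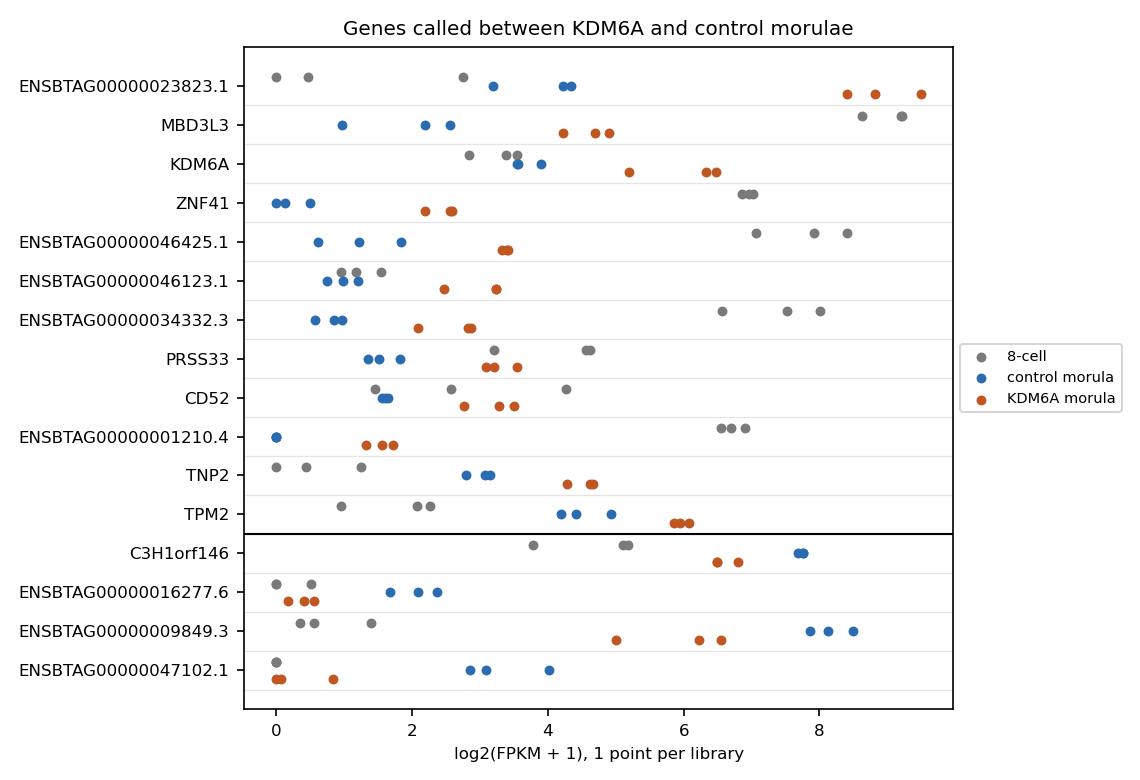
Each point is 1 library, on a log2(FPKM + 1) axis, for the 16 genes called between KDM6A and control morulae, with 12 rises above the black line and 4 falls below it. The KDM6A and control points do not overlap in any row, and 5 of the risen rows lie far to the right in 8-cell embryos.

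The number of calls depended on single libraries. Without KDM6A replicate 1 it was 725 (365 rises, 360 falls), without control replicate 2 it was 8, without control replicate 3 or KDM6A replicate 2 it was 3, and without KDM6A replicate 3 it was 1. It was 2510 with array weights, 28 after quantile normalization, 25 on the TPM scale, 10 with all 9 libraries in the fit and 0 with no filter. The array weights, estimated from the same libraries, were 3.36 for KDM6A replicate 2 and 2.93 for control replicate 3. The others had weights of 0.344 to 0.702, so the 2510 calls lean on 1 library per group. KDM6A replicate 1 correlated at 0.982 to 0.983 with the 3 controls and at 0.975 and 0.970 with KDM6A replicates 2 and 3 across the 9777 genes tested, while control replicates 1 and 2 correlated at 0.976 with each other.

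**Figure D2:**
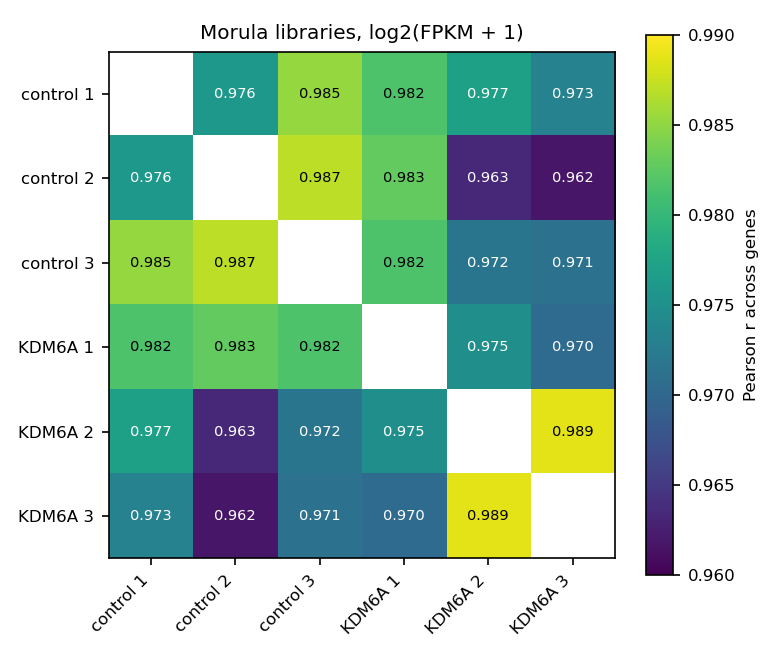
Pearson correlation of log2(FPKM + 1) across the 9777 genes tested, for each pair of the 6 morula libraries. KDM6A replicates 2 and 3 share the highest value, 0.989, and KDM6A replicate 1 lies at 0.982 to 0.983 with the controls.

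Other genes named by the rule did not pass the threshold and are given as values. HSPB1, a small heat shock protein, was at 419 ± 38.4 FPKM in controls and 721 ± 50.8 in KDM6A morulae, and MT2A, a metallothionein, at 207 ± 68.8 and 482.5 ± 43.3. DUOXA2 was at 29.4 ± 7.96 and 79.99 ± 20.9 FPKM, and LGALS7, a galectin, at 994 ± 119 and 1621 ± 102. GATA3 and GATA2, transcription factors of the trophectoderm (the outer layer that forms the placenta), were at 7.65 ± 0.66 and 2.90 ± 0.413 FPKM in controls and at 2.73 ± 0.501 and 0.643 ± 0.248 in KDM6A morulae. PFDN4 was at 158 ± 19.9 and 79.1 ± 9.67, TDRKH at 3.81 ± 0.123 and 1.203 ± 0.0404, CTDSPL at 3.87 ± 0.330 and 1.19 ± 0.197, and GCSH at 2849 ± 319 and 1685 ± 244. CCN2, NUCKS1 and PKIA completed the set, with log2 fold changes of -1.04, -1.42 and -1.37. Limma adjusted p-values of these 13 genes were from 0.0552 to 0.0858. Of the 10 alternatives run gene by gene, GATA2 was tested in 7 and passed the threshold in 2, and each other gene passed in 1 to 3. The highest limma adjusted p among the alternatives not passed was 0.421. The pluripotency factors POU5F1 (146 ± 21.6 and 106 ± 55.2 FPKM), NANOG (42.4 ± 2.10 and 53.6 ± 18.8) and SOX2 (13.1 ± 2.38 and 14.4 ± 2.42) showed no call, with adjusted p of 0.445 to 0.833.

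Of the 20 gene lists, only the genes of oxidative phosphorylation passed as a set with the preset correlation, lower in KDM6A morulae by a small amount. The median log2 fold change over 72 members was -0.16, with 18 above 0 and no member called, over all genes or adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.998 with an estimated correlation). The members with the smallest p-values included NDUFS4 at 298 ± 52.7 FPKM in controls and 187.5 ± 8.74 in KDM6A morulae and NDUFA5 at 1392 ± 183 and 1047 ± 29.4, at adjusted p of 0.179 and 0.283. The set was no longer past the threshold after quantile normalization (adjusted p = 0.268) or without control replicate 3 or KDM6A replicate 2, and its highest adjusted p over the replicates left out was 0.326. Among the 10 splits of these 6 libraries into 3 and 3, 9 gave at least 1 list, the real one included. The highest other split gave 5, so 1 list is no more than regrouped libraries gave.

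No other list passed with all 6 libraries and the filter of 1 FPKM. With the preset correlation, camera put cell adhesion and junctions lower at a filter of 5 FPKM (adjusted p = 0.0273) and without control replicate 1 (0.0231), and cytosolic ribosomal proteins lower without control replicate 2 (0.0242) or KDM6A replicate 3 (0.00514). Oocyte and maternal transcripts were lower without control replicate 2 (adjusted p = 0.000399, median -0.40), while their median was 0.31 without control replicate 1. Adjusted over the list alone, 3 trophectoderm members were higher and 4 lower of 27, with none called over all genes. PTGES (110 ± 11.9 and 187 ± 27.2 FPKM) and FABP5 (23.8 ± 6.75 and 43.3 ± 5.11) were on the higher side and GATA2 and GATA3 on the lower. Of 44 apoptosis, p53 and cell stress genes, 3 were higher adjusted over the list alone and 0 over all genes, with CDKN1A, the p53-induced cell cycle inhibitor, at 1.15 ± 0.448 and 3.63 ± 1.05 FPKM and SOD2 at 4.96 ± 2.35 and 10.7 ± 0.774. Of 35 polycomb-target developmental regulators, none was called over all genes and 2, GATA2 and GATA3, were lower adjusted over the list alone. Among 27 genes of H3K27 methylation and polycomb, KDM6A alone was called by either adjustment. Among 21 donor fibroblast markers TPM2 rose, and 3 were higher and 2 lower adjusted over the list alone, TIMP1 at 295 ± 14.4 and 481 ± 59.6 FPKM and CCN2 at 32.8 ± 2.76 and 15.6 ± 2.50 among them. The 8 sperm and testis-type transcripts held 1 call, TNP2. Primitive endoderm (17 tested) had 1 higher and 2 lower adjusted over the list alone, cell adhesion and junctions (45) had 1 lower, PRKCI at 48.4 ± 5.62 and 24.3 ± 5.09 FPKM, and cumulus and granulosa (9) had 1 higher, with none called over all genes in any of them.

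For the remaining lists, no member was called by either adjustment. These were DNA methylation and H3K9 or H3K4 regulators (31 tested), embryonic genome activation (18), pluripotency and inner cell mass (22), oocyte and maternal transcripts (29), glycolysis and hexose uptake (30), lipid and sterol synthesis (40), cytosolic ribosomal proteins (72), imprinted genes (11), interferon response (16) and cell cycle and replication (58). UBTFL1 (7.49 ± 0.550 and 17.9 ± 6.95 FPKM), KLF17 (46.8 ± 26.4 and 91.75 ± 23.6) and ZSCAN4 (40.4 ± 9.23 and 63.7 ± 11.8), of the genome activation list, had adjusted p of 0.227 to 0.287, and KDM5B, an H3K4 demethylase, was at 11 ± 1.195 and 20.1 ± 2.89 (0.179). The median, mean and test differed in sign for the H3K27, pluripotency, polycomb-target and cell cycle lists, with medians from -0.021 to 0.0253. Oocyte and maternal transcripts stood higher in control replicate 1 than in the other controls, with list means of 3.21, 1.78 and 2.31 on the log2(FPKM + 1) scale in control replicates 1, 2 and 3 and 2.28 to 2.42 in KDM6A morulae.

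**Figure D3:**
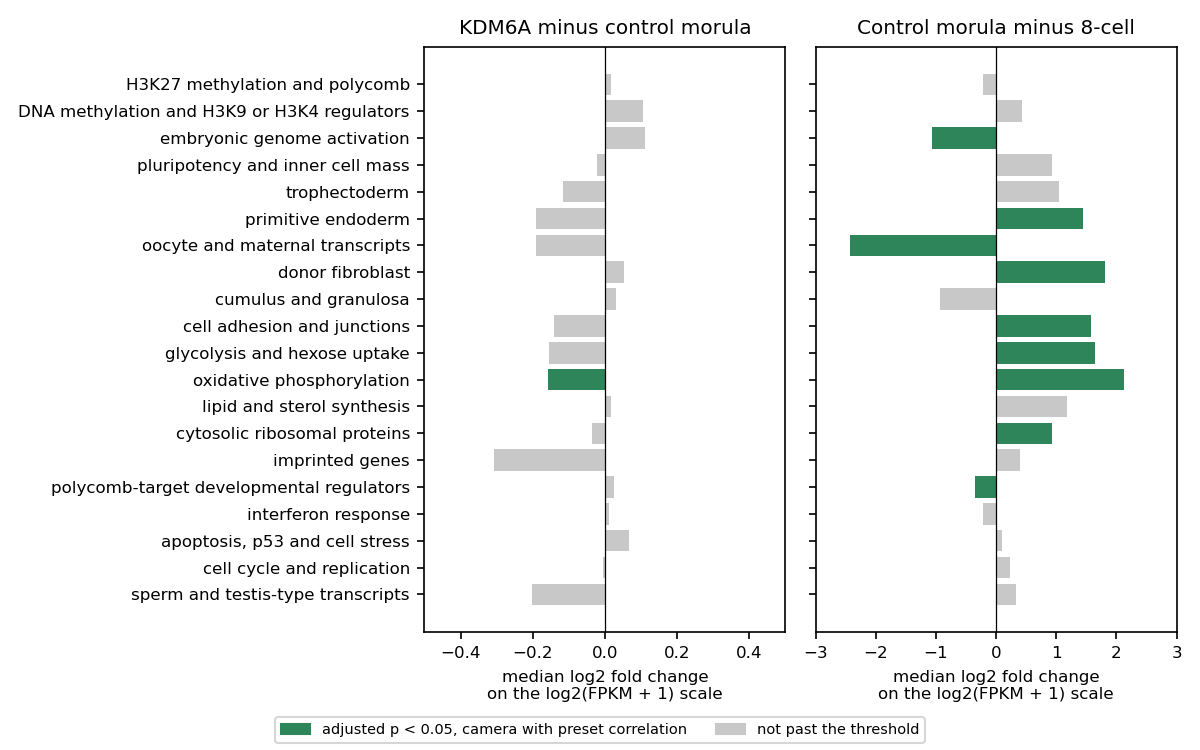
Bars give the median log2 fold change, on the log2(FPKM + 1) scale, of the tested members of each of 20 gene lists, for KDM6A minus control morulae (left) and control morulae minus 8-cell embryos (right), with different axis ranges. Green bars are the 1 and 9 lists past the threshold with the preset correlation, none of which holds with an estimated one.

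X-linked genes were compared with autosomal genes because X dosage is known to be disturbed in cloned embryos. The median log2 fold change of 296 X-linked genes was -0.0487 and that of 8727 autosomal genes -0.0146, a difference of -0.0341, and 45.9% of X-linked against 48.3% of autosomal genes were above 0. The camera test of limma, run across all genes as a single test, gave an adjusted p = 0.574 equal to the unadjusted one. Of the X-linked genes 2 rose, KDM6A itself, whose mRNA was injected, and ZNF41, and 0 fell. The difference turned positive without control replicate 3 (0.0194) or KDM6A replicate 2 (0.00209).

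Control morulae and 8-cell embryos differed in most genes, in a comparison in which stage and source series cannot be told apart. Genes higher in control morulae included TBC1D32, at 360 ± 8.97 FPKM against 1.36 ± 0.890 in 8-cell embryos (n = 3 each), LGALS3, a galectin (351 ± 94.7 against 4.35 ± 1.85), ENPEP, a membrane aminopeptidase (127 ± 34.8 against 0.727 ± 0.726), S100A5 (373 ± 63.5 against 2.68 ± 3.78) and BRB (380 ± 116 against 2.42 ± 3.13). LITAF, PPP1R14A, RABAC1 and HINT2 also rose, with log2 fold changes of 6.06 to 6.18, and the metallothionein MT1A was at 86.3 ± 20.7 FPKM in control morulae and listed at 0 in the 3 8-cell libraries. Higher in 8-cell embryos were BECN2 (1325 ± 679 against 6.38 ± 1.85 FPKM), the BTG-family gene BTG4, known for clearing maternal mRNA (5911 ± 2654 against 158 ± 192), the oocyte-secreted OOSP2 (2457 ± 1452 against 56.4 ± 78.4), MBD3L3 (526 ± 113 against 3.13 ± 1.99), ZNF41 (123 ± 7.09 against 0.167 ± 0.215) and the transcription factor FOXO1 (119 ± 34.0 against 0.323 ± 0.210). TMSB4, a thymosin whose reads may be shared with related copies, FANK1, CROT and TAF9 fell with log2 fold changes of -7.31, -6.12, -5.74 and -5.47. Limma adjusted p-values of these 20 genes were at most 0.000402.

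**Figure D4:**
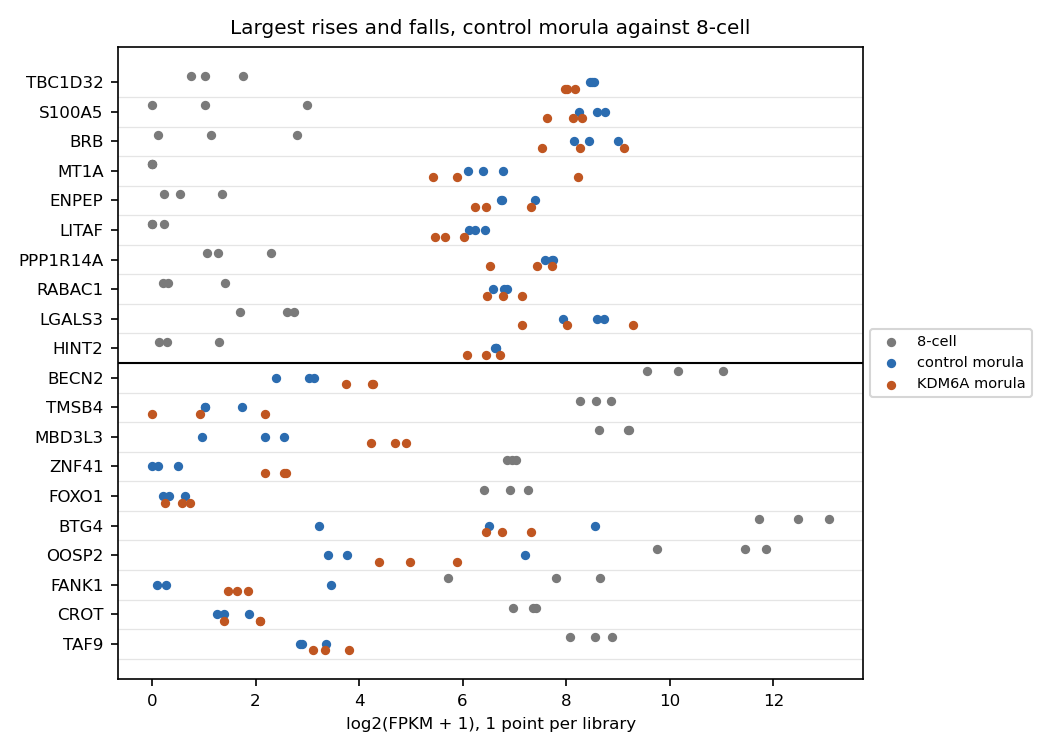
Each point is 1 library, on a log2(FPKM + 1) axis, for the 10 largest rises (above the line) and the 10 largest falls (below it) from 8-cell embryos to control morulae, with KDM6A morulae shown beside them. The highest control is replicate 1 for BTG4 and FANK1 and replicate 3 for OOSP2.

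Among 10048 genes tested, 4293 were higher in control morulae and 2719 lower (limma). The median log2 fold change of all genes was 0.35, and 0.042 and 0.097 after quantile normalization and median-of-ratios scaling, so directions are relative to that median. Quantile normalization gave 3557 higher and 3404 lower, 51.1% higher in place of 61.2%. Of the genes always given, POU5F1 rose from 8.40 ± 2.18 to 146 ± 21.6 FPKM and SOX2 from 1.88 ± 1.01 to 13.1 ± 2.38, GATA3 rose from 2.91 ± 2.11 to 7.65 ± 0.66, and NANOG fell from 86.8 ± 24.9 to 42.4 ± 2.10. SUZ12 fell from 77.2 ± 10.3 to 28.4 ± 4.66 FPKM and EED from 109 ± 11.7 to 63.8 ± 12.4. EZH2 (22.05 ± 3.154 and 25.1 ± 4.16) and KDM6A (8.76 ± 2.37 and 11.8 ± 1.81) showed no call, and the sign of the EZH2 change turned after quantile normalization or median-of-ratios scaling.

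Energy metabolism and translation genes were higher in control morulae. Of 72 oxidative phosphorylation genes 69 rose and 0 fell, among them UQCR11 (21.0 ± 2.19 to 480 ± 103 FPKM) and CYC1 (11.8 ± 7.25 to 225 ± 43.6), with a list median of 2.13 (camera adjusted p = 2.31e-14, and adjusted p = 0.306 with an estimated correlation). Of 30 glycolysis and hexose uptake genes 22 rose and 1 fell, including TALDO1 (35.5 ± 19.65 to 464 ± 62.9 FPKM) and GAPDH (15.04 ± 2.10 to 218 ± 96.9), at camera adjusted p = 0.000884 and adjusted p = 0.306 with an estimated correlation. Of 71 cytosolic ribosomal protein genes 54 rose and 1 fell, RPS3 from 775 ± 195 to 4575 ± 126 FPKM and RPL3 from 270 ± 58.9 to 1046 ± 72.2, with a median of 0.92 (camera adjusted p = 9.45e-05, and adjusted p = 0.618 with an estimated correlation). After quantile normalization 45 of these rose and 9 fell.

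The cell adhesion, primitive endoderm and donor fibroblast lists were also higher in control morulae. Of 44 cell adhesion and junction genes 29 rose and 9 fell, the tight junction gene CLDN6 from 15.1 ± 16.5 to 627 ± 147 FPKM and PERP from 3.53 ± 0.439 to 111 ± 20.2 (camera adjusted p = 0.0196, and adjusted p = 0.306 with an estimated correlation). Of 17 primitive endoderm genes 12 rose and 2 fell, among them FGFR4 (0.41 ± 0.281 to 20.7 ± 3.46 FPKM) and LAMB1 (2.38 ± 0.636 to 30.6 ± 13.55), at camera adjusted p = 0.0257 and adjusted p = 0.527 with an estimated correlation. This list lost its call when any 1 of the 6 libraries was left out, with adjusted p up to 0.389. The set of genes tested changed as well, since the filter stayed at 3 libraries. Of 21 donor fibroblast markers 14 rose and 4 fell (camera adjusted p = 0.0241, and adjusted p = 0.306 with an estimated correlation). Those that rose most were FN1 (0.617 ± 0.765 to 99.65 ± 20.85 FPKM), TIMP1 (9.08 ± 5.64 to 295 ± 14.4), ANXA1 and SPARC, which code for matrix proteins, a protease inhibitor and an annexin that many cell types make. That call was lost when any of the 3 controls was left out, with adjusted p up to 0.078. Genes at 1 FPKM in controls alone then left the test, and 9106 to 9129 genes were tested in place of 10048. The loss therefore need not reflect any single library.

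Maternal transcripts and early activated genes were lower in control morulae. Of 39 oocyte and maternal transcripts 32 fell and 1 rose, NPM2 from 71.8 ± 31.8 to 2.24 ± 1.79 FPKM and NLRP8 from 50.6 ± 8.77 to 1.35 ± 0.993, with a median of -2.42 (camera adjusted p = 8.38e-10, and adjusted p = 0.370 with an estimated correlation). Of 19 genome activation genes 12 fell and 2 rose, with KLF17 falling from 197 ± 94.6 to 46.8 ± 26.4 FPKM and TRIM77 from 35.2 ± 4.10 to 7.80 ± 5.74, while POU5F1 was a riser (camera adjusted p = 0.0196, and adjusted p = 0.306 with an estimated correlation). The largest fall in this list was H1-8, from 20.1 ± 2.30 to 4.16 ± 6.12 FPKM. The oocyte list also holds H1-8, so these lists overlap. Of 46 polycomb-target developmental regulators 21 fell and 12 rose (camera adjusted p = 0.0257, and adjusted p = 0.306 with an estimated correlation). TFAP2B fell from 25.9 ± 6.82 to 0.85 ± 0.911 FPKM and ALX1 from 48.4 ± 7.22 to 5.77 ± 3.76, and OTX2 rose from 2.13 ± 0.7605 to 55.4 ± 13.4. This call was lost when any of the 3 8-cell libraries was left out, with adjusted p up to 0.494. Genes at 1 FPKM in 8-cell embryos alone then left the test, and 9481 to 9506 genes were tested in place of 10048. This loss too need not reflect any single library.

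Other lists did not pass as sets but held many calls, in a comparison that called 69.8% of all 10048 genes tested. In H3K27 methylation and polycomb 8 rose and 11 fell of 26, L3MBTL2 and PHC1 rising and RYBP and RNF2 falling. In DNA methylation and H3K9 or H3K4 regulators 15 rose and 9 fell of 32, UHRF1 falling from 58.8 ± 18.75 to 1.98 ± 0.901 FPKM and DNMT1 from 55.2 ± 18.7 to 8.27 ± 2.28, and DNMT3A rising from 0.803 ± 0.437 to 10.9 ± 1.625. In trophectoderm 15 rose and 6 fell of 28, KRT18 from 0.253 ± 0.191 to 46.6 ± 17.7 FPKM and PTGES from 1.89 ± 1.95 to 110 ± 11.9 among the risers. In pluripotency and inner cell mass 11 rose and 6 fell of 22, and in lipid and sterol synthesis 27 rose and 9 fell of 42, led by PLIN2, a coat protein of lipid droplets (11.5 ± 1.94 to 201 ± 19.6 FPKM). The counts were 25 and 16 of 56 for cell cycle and replication, 16 and 15 of 44 for apoptosis, p53 and cell stress, 5 and 6 of 15 for interferon response, 4 and 2 of 10 for imprinted genes, 2 and 5 of 9 for cumulus and granulosa, and 3 and 4 of 9 for sperm and testis-type transcripts. Counts adjusted over the list alone differed by at most 1 in each direction for each of the 20 lists. Since camera compares a list with all other genes, its direction was down for several lists with a median above 0, such as apoptosis (0.089) and cell cycle (0.23).

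KDM6A morulae differed from 8-cell embryos in a similar number of genes, 4121 higher and 2568 lower of 10024 tested, and 3362 and 3225 after quantile normalization. Whether the 2 stage comparisons differ is answered by the comparison of KDM6A and control morulae. Fold changes of KDM6A minus control morulae and of control morulae minus 8-cell embryos had a covariance of -0.137 across 10431 genes. For unchanged groups sharing the same controls it was -0.0298 (SD 0.0259, 200 simulations), with a range of -0.117 to 0.00813. Pearson's r was -0.239 and Spearman's rho -0.239 across genes, which are not independent replicates. The simulated r was -0.393, but the simulated groups hold no change with stage. In the real data that change widens the fold changes by which r is scaled, so the simulated and observed r cannot be compared. Of 9398 genes tested in both, 6 of the 12 rises in KDM6A morulae fell from the 8-cell stage to control morulae (2.71 by independent lists), 3 rose (5.48), and the 4 falls in KDM6A morulae all rose (1.83). Simulated unchanged groups shared 0 calls in each of 50 draws, but only 1 draw held calls in both comparisons, so this 0 is no measure of what shared controls add. Calls arose in 7 draws for each comparison, up to 750 and 1057, above the 16 genes called between KDM6A and control morulae. Each of those draws had used the deviations of 1 library more than once, which narrows the simulated spread. The 3 controls are too few to split, so part of the overlap may come from sharing them. The covariance was -0.0624 without control replicate 2 and -0.249 without control replicate 1, and it was -0.220, -0.104 and -0.0911 without KDM6A replicates 1, 2 and 3. The values without control replicate 2 or KDM6A replicate 2 or 3 lie inside the simulated range. No simulation was run with a replicate left out.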

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

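The tests on oocyte transcripts given here were chosen after the result was seen, and the choice of genes in the test of 8-cell embryos was changed afterwards. Control morula replicate 1 carried 4.339% of its summed FPKM in rows with no annotated gene identifier, which the other 8 libraries do not list and no comparison used. A further 23 genes with a mean of at least 1 FPKM were listed for the 8-cell libraries alone, so they entered no comparison with morulae.

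Oocyte and maternal transcripts stood higher in control morula replicate 1 than in replicate 2 for 37 of 39 list members, and above both other controls for 36, with BTG4 at 374, 8.35 and 90.4 FPKM and BMP15 at 34.1, 1.00 and 10.9 in replicates 1, 2 and 3. Embryos like those of the 8-cell libraries in that pool would raise other genes abundant at that stage by a like share. Over 65 such genes the median gain above replicate 2 was 0.763% of the 8-cell level (bootstrap interval 0.203 to 1.88), with quartiles of -0.034% and 7.28%. It was 5.48% (1.96 to 20.9) over oocyte genes chosen by the same rule, but only 6 met it. Over the 22 oocyte genes with at least 20 FPKM at the 8-cell stage it was 17.7% (15.9 to 21.0). For the genes covered, these medians argue against such embryos as the source. The upper quartile shows that some of the 65 genes gained as much as the 6 oocyte genes. Separate quantification of that library with its extra rows stays open, since the test of it, the list lying 1.10 log2 units (0.555 to 1.68) above replicate 2 after the median of all genes was subtracted, measures the pattern again and decides nothing. Beyond a pool mixed with 8-cell embryos, no biological explanation was tested, since the labels give no difference between the control pools.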

How the results depend on the processing

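The threshold of 0.10 was the only alternative chosen after the data were seen. Of the KDM6A and control comparison, the 16 genes called became 0 with no filter, 25 on the TPM scale, 28 after quantile normalization, 10 with all 9 libraries in the fit, 2510 with array weights and 62 at an adjusted p under 0.10, and from 1 (without KDM6A replicate 3) to 725 (without KDM6A replicate 1) over the replicates left out. The count stayed at 16 with pseudocounts of 0.1 and 0.5, a robust prior and median-of-ratios scaling. Lists past the threshold, 1 in the report, became 0 with an estimated correlation, 0 after quantile normalization and 2 with a filter of 5 FPKM, and 0 to 3 over the replicates left out. The KDM6A log2 fold change ran from 2.10 to 2.73 over the replicates left out. The X-linked difference ran from -0.0625 to 0.0194, and was above 0 without control replicate 3 (0.0194) or KDM6A replicate 2 (0.00209). EZH2 changed sign between KDM6A and control morulae, from -0.20 to 0.0354 over the replicates left out, with 0.0289 without KDM6A replicate 3, and EED ran from -0.0710 to 0.16, with -0.0701 without control replicate 3, -0.0121 without KDM6A replicate 1 and -0.0179 without KDM6A replicate 3. From 8-cell embryos to control morulae EZH2 was at -0.00763 after quantile normalization and -0.0891 after median-of-ratios scaling. The 9 lists past the threshold in that comparison became 0 with an estimated correlation. Its 7012 genes and the 6689 of KDM6A morulae against 8-cell embryos stayed within 1.5 times under each alternative, at 5286 to 6528 and 4993 to 6118 over the replicates left out. The covariance was -0.266 with a pseudocount of 0.1, -0.164 with a filter of 5 FPKM, and -0.249 to -0.0624 over the replicates left out. With no filter more genes enter the adjustment. Leaving a replicate out removes genes that only the reduced group held at 1 FPKM, as the filter stayed at 3 libraries. For these changes the cause was not tested. Depth is unknown, so what it limits could not be stated.

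With the replicate number as a block, 1 gene was called between KDM6A and control morulae, and the KDM6A log2 fold change of 2.33 had an adjusted p of 0.0804. Deviations of same-numbered libraries from their group means correlated at -0.210, -0.216 and 0.133. Differently numbered libraries of these groups gave -0.183 to 0.285. The values show no pairing by number, but 3 correlations are too few to exclude one.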

Other observations

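The tests of lagging embryos, of the injection and of a mislabelled library were chosen after the result was seen, and the choice of genes in the test of lagging embryos was changed after its result was seen. The genes called between KDM6A and control morulae included 5 rows that were at 104 to 526 FPKM in 8-cell embryos, among them MBD3L3 and ZNF41. Their gain in KDM6A morulae came to 1.83% to 3.96% of the 8-cell level. Embryos lagging at the 8-cell stage may account for this. Over 67 genes outside the oocyte list chosen as abundant at that stage against the controls, these 5 included, the median gain was 0.723% (bootstrap interval 0.544 to 1.10). Without control replicate 1 it was 1.41% (0.904 to 2.18), an interval that reaches the 1.83% needed. Of the 67 genes, 22 gained at least 1.83%, and 28 did so without control replicate 1. The first choice, 65 genes abundant against all 6 morulae, gave 0.662% (0.106 to 0.751) and 1.16% (0.668 to 1.70), below what is needed, but it leaves out genes for being high in KDM6A morulae, so the explanation stays open and depends on this choice. The injection itself and the encoded KDM6A cannot be told apart, because the design holds 0 libraries of morulae injected with another mRNA.

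KDM6A morula replicate 1 correlated at 0.982 to 0.983 with the controls and at 0.975 and 0.970 with the other KDM6A morulae. A mislabelled control library is argued against, since its KDM6A transcript lay 21.79 FPKM above the highest control, where the controls spanned 3.14 FPKM. A pool in which part of the embryos carried no effect would place the changed genes where KDM6A lies, at 0.333 of the way from the control mean to the mean of the other KDM6A morulae. The median position was 0.110 (0.0733 to 0.157) over the 724 genes other than KDM6A called without that library, with quartiles of -0.0697 and 0.369 and medians of 0.0376 for risen and 0.236 for fallen genes. This decides nothing, although the bound set before the result was seen was met, because genes selected in the other libraries overstate their effects there and so lower the position, and the explanation stays open.

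Each 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split of KDM6A and control morulae called 16 genes and the highest other split 1, and 1 of the 10 splits, the real one, gave as many. For the control morula and 8-cell comparison the values were 7012 and 0, and for KDM6A morulae against 8-cell embryos 6689 and 0, again with 1 of 10 splits as large. Any other split mixes the stages, so the stage difference widens the spread within its groups. Few calls were then bound to follow, and the 0 says nothing about chance. For lists the real split of KDM6A and control morulae gave 1 and the highest other 5, with 9 of 10 splits as large. With an estimated correlation between genes 0 lists passed in the real split, and whether correlated list members or a structure among the libraries lies behind the other splits was not tested. Control morulae against 8-cell embryos gave 9 lists and at most 6 in another split. The X-linked difference had a size of 0.0341 against 0.0762 in the highest other split, with 5 of 10 as large.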
